A study of Mus musculus with 17 samples.

How the data were processed

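The values analysed were log2 ratios of the 2 channels of cDNA arrays, as deposited by the authors in 1 table of 20794 rows and 17 columns. The image analysis, background correction, normalization and spot filtering are not given in the sources used here. The log base was inferred from the values: they were centred near 0 and their tails ended near 17 in size, slightly beyond what a log2 ratio of 16-bit readings reaches, while a natural or decimal logarithm of that size would need ratios far beyond it. The base thus stays an inference. Array medians lay between -0.11 and 0.09 (adults) and between -0.02 and 0.03 (embryos). Missing values numbered 97 to 716 per array. Per the labels' protocols, mutant RNA and a wild-type pool were labelled indirectly with Cy3 and Cy5. The labels name the same pool animals on all fetal arrays but call that pool male on 2 arrays and female on 4.

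Probe names came from the platform's annotation: 12771 probes had 1 gene symbol (9030 genes), 0 had several and 8023 had none. All 12771 Entrez IDs were found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. Since the files state no genome build, no coordinates are given. A gene was the mean of its probes, and an unnamed probe was kept on its own.

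The row naming was tested before use, since the value table pairs rows with IDs without scanner files. Probes of the same gene (5055 pairs) should correlate. For the adult mean their Spearman correlation was highest, 0.0574, at an offset of 0 rows among 121 offsets up to 60 rows either way. For the fetal mean it was highest, 0.0821, at an offset of 11 rows, against 0.0015 as deposited and at most 0.0638 at any other offset. The fetal mean also correlated best with the adult dye profile at 11 rows, at 0.375, against 0.0189 as deposited. In 20 of 21 blocks of 1000 probes the same offset was best, with correlations of 0.301 to 0.470, and in the last, shorter block it was not, with 0.118. Embryo 6 alone showed no such dye profile, at 0.019, and embryo 5 no agreement of same-gene probes, at 0.004. Fetal rows were therefore moved by 11 rows for probes up to 20000, and the remaining 794 fetal rows were kept unnamed. Afp probes were among the same-gene pairs used. This choice was made after seeing the data, and fetal results with the names as deposited are given as an alternative.

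The design fixed before the data were examined said that arrays with the mutant in Cy3 be turned in sign if dye-swap pairs correlated negatively. They did (median Spearman correlation -0.287), but opposite-dye arrays of different animals did so as well (-0.251). The columns with the mutant in Cy3 carried trailing zeros in at most 0.1% of values, against at least 8.4% in all others. Their values beyond 10 in size were all negative, where those of all other arrays were all positive. The realigned fetal mean, with the mutant in Cy5, correlated at 0.291 with the adult mean of the same orientation and at -0.375 with the other. These columns were therefore taken as already turned to mutant over pool by the authors and left as deposited, which departs from the fixed rule. The turned result is given as an alternative. Going against this choice, the deviations of an animal's arrays correlated at -0.101 over all probes, with 114 of 120 matchings of animals as high. Over the 37 gene lists this correlation ran from -0.481 for cholangiocytes to 0.445 for hepatocyte secreted proteins, so it does not settle the direction. The overall sign could not be checked with sex-linked genes as planned and rests on the fetal value of Afp, which departs from the plan as well. Arrays of the same orientation did not correlate clearly below 0 (lowest Pearson r -0.00397).

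Arrays of an animal were averaged first. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes): the log ratio against 0 for adults and for embryos, and 2-group fits for adult minus fetal (arrays with the mutant in Cy5) and for female minus male embryos. Features needed a value in 4 of 6 animals per group, or in at least 2 of each sex and 4 in all. Benjamini-Hochberg adjusted p under 0.05 was the threshold. For fits, values were used as deposited without further centring. The adult dye profile was the difference between the arrays of both orientations divided by 2, averaged over 5 animals. The 37 gene lists fixed beforehand were tested with camera (preset correlation 0.01 and estimated) and fry on features without missing values, adjusted over 36 lists per comparison; the sex-linked list was given per gene where measured, Kdm5d in adults alone and Zfy1 in both ages. The text names Afp, Alb, Afm, Gc and sex-linked genes, up to 10 rises and 10 falls that passed with the same sign in every animal or with groups apart, the 5 smallest p where fewer than 10 features passed, and examples from up to 4 members of each called list. The fry calls of the albumin family in the embryos and between the ages are left out of the results, since the list holds the targeted gene.

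The fits were tested on simulated data with 200 changed features. At a log2 change of 1, they recovered 69% for the adult design (17053 features), 90.5% for the fetal design (17295), 57% for adult minus fetal (17053) and 0% for the sexes (17295), where a change of 2 gave 88%. At a change of 0.5, they recovered 24.5% for the fetal design and 0% for the adults, for adult minus fetal and for the sexes. The simulated spread was that of the data without values beyond 10 in size, which the reported fits kept. The spread simulated for adult minus fetal was that of the adults in both groups, and at most 6.12% of calls were false where over 50 features were recovered. Alternatives covered centring, scaling (limma normalizeMedianAbsValues after centring), single probes, missing values, the variance model, thresholds, dye handling and left-out animals. Alternatives added after seeing the data were the turned arrays, the deposited row names, leaving out values beyond 10 in size or the probes after the last aligned block, a dye profile scaled to each embryo, and fry counts. A gene that passed neither in the reported fit nor in an alternative was counted as unchanged even where its sign differed, and a count as unchanged within 1.5 times. Python 3.11.15 and pandas 2.3.3 read the table.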

Results

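Liver RNA of Afp knockout mice was hybridised to 2-colour cDNA arrays against a pool of wild-type liver RNA, in adult males and in embryos. The adult part held 11 arrays of 6 mutant males aged 17 weeks, 5 of which were measured with both dye orientations and 1 with the mutant in Cy5 alone. The fetal part held 6 arrays of 6 mutant embryos, 3 male and 3 female, all with the mutant in Cy5. The labels gave the embryonic day as 7.5 for tissue they call fetal liver. That day was not checked and is kept here as a label, not taken as the age of the embryos. Each array carried between 20078 and 20697 values of 20794 probes. All values below are log2 ratios of mutant over pool, given as mean ± SD between animals. Their direction and, for the embryos, their row naming were inferred from the values. The plot of correlation by row offset bears on the row naming alone. No wild-type animal was measured on its own, so each test leaves out the spread among wild-type animals, and the number of animals limits the precision.

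**Figure D1:**
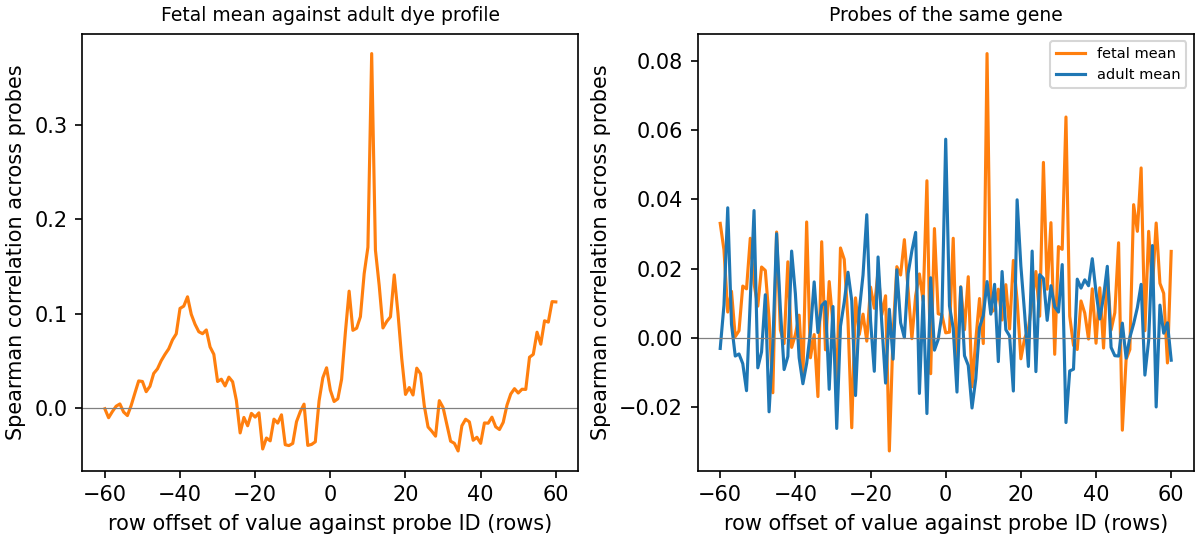
The plot shows, for each offset in rows between a value and its probe name (horizontal axis), the Spearman correlation across probes (vertical axis) of the fetal mean with the adult dye profile on the left and of probes of the same gene on the right, for the fetal mean in orange and the adult mean in blue. The fetal curves peak at 11 rows, at 0.375 and 0.0821, and the adult curve at 0 rows, at 0.0574.

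The fetal comparison asked which liver transcripts differed between Afp mutant embryos and the wild-type pool. Afp, the targeted gene, which encodes the main serum protein of the fetus, lay at -8.40 ± 0.23 (SD, n = 6), lower in 6 of 6 embryos, with limma's adjusted p = 1.25e-08. Its 3 probes averaged -8.49, -8.82 and -7.90. The first 2 of these probes read the same value in embryo 1 (-8.75) and in embryos 4 and 5 (-8.45 each). The remaining Afp probe stood a whole log2 unit above them in embryo 1, at -7.75, and in embryo 5, at -7.45. Equal values and whole steps go with readings at a limit. The size of the fall may thus be a bound, and its SD may reflect rounding. Whether the mutant channel lay at its floor cannot be read from the ratios. Afm, which encodes afamin and belongs to the albumin gene family, rose by 0.83 ± 0.16 (SD, n = 6, adjusted p = 0.0211). Alb, encoding serum albumin, averaged 0.27 ± 0.23 and did not pass (adjusted p = 0.170), and stood at 0.031 with the adult dye profile subtracted. Gc, the remaining family member, was not analysed here, since no probe carried its symbol.

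**Figure D2:**
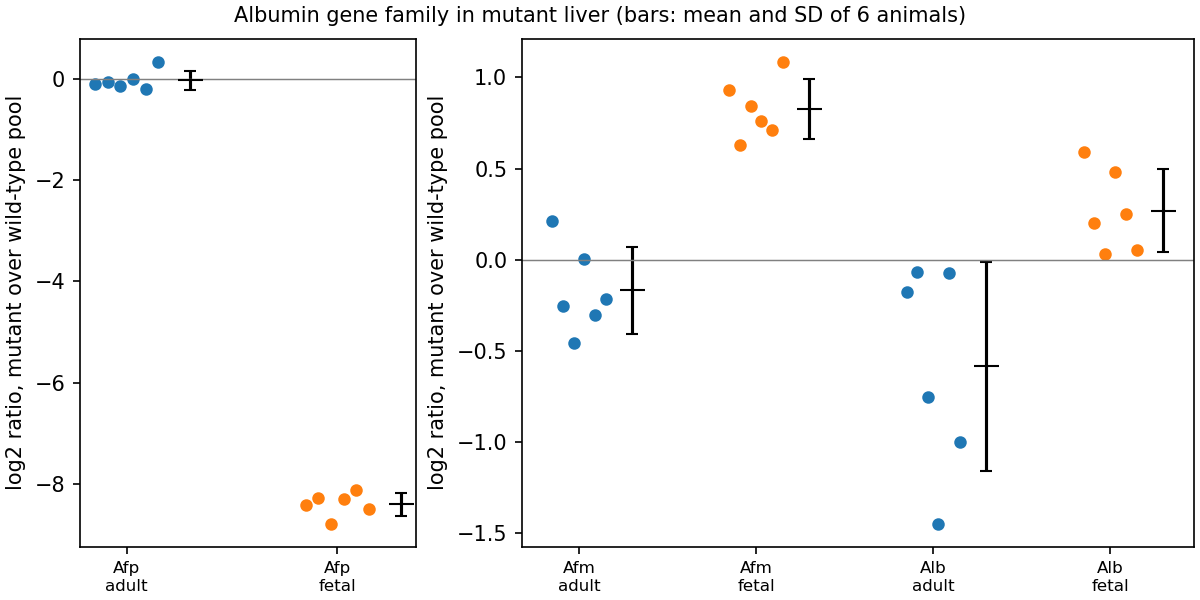
The plot shows the log2 ratio of mutant over wild-type pool (vertical axis) of Afp on the left and of Afm and Alb on the right, with 1 point per animal and a bar for the mean and SD of 6 animals. Afp averaged -8.40 in the embryos and -0.03 in the adults.

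In all, 26 of 17242 features passed in the embryos, 10 higher and 16 lower, of which 10 were named genes. Among the named genes, Rnase4, a secreted ribonuclease, rose most, by 1.08 ± 0.22 (n = 6, adjusted p = 0.0176). Sc5d, an enzyme of late cholesterol synthesis, rose by 0.56 ± 0.06 (adjusted p = 0.0330). Ddx3x, an X-linked RNA helicase, rose by 0.71 ± 0.22 (adjusted p = 0.0467), but its adult dye profile, measured from the dye swaps, was 0.75, and it stood at -0.037 with that profile subtracted. The falls included the acinar pancreas genes Cela2a at -1.30 ± 0.47 and Cpa1 at -1.17 ± 0.43 (each with adjusted p = 0.0467), Prap1 at -1.22 ± 0.41 (adjusted p = 0.0408), Dhrs7 at -0.77 ± 0.21 (adjusted p = 0.0405) and Ccdc178 at -0.62 ± 0.15 (adjusted p = 0.0434). With the dye profile subtracted, Cpa1 stood at -0.68 and Ccdc178 at -0.17, and Ccdc178 no longer passed. The exocrine pancreas list as a whole was not called, with 8 of 14 genes below 0 and 6 above (camera adjusted p = 0.231, fry adjusted p = 0.0790), and 6 fell and 3 rose adjusted over the list alone, against 2 and 0 over all genes. An unnamed feature, probe 19614, lay at -5.62 ± 0.50 (adjusted p = 1.44e-05). It was named after its values were seen. Mutant and Cy5 coincide on all fetal arrays, and leaving out embryo 1, 2, 3 or 5 left 2 features, embryo 4 left 4 and embryo 6 left 5, with Afp passing in 6 of 6 such fits, Rnase4 in 2 and Afm in 1. Sc5d, Ddx3x, Cela2a, Cpa1, Prap1, Dhrs7 and Ccdc178 each passed in 0. With the adult dye profile subtracted as measured, 4986 features passed.

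Camera with its preset correlation placed transcripts of the translation machinery and of hepatocyte products above other genes in the embryos. None of the 7 lists it called kept its call with an estimated correlation, where the smallest adjusted p = 0.584. Of 56 cytosolic ribosomal protein genes, 44 had a mean above 0, and 20 rose with adjustment over the list alone, against 0 with adjustment over all genes (median 0.20, camera adjusted p = 6.47e-07). Examples were Rps29 at 0.60 ± 0.28, or 0.30 with the dye profile subtracted, and Rps13 at 0.31 ± 0.09. Of 27 genes for hepatocyte secreted proteins, 23 lay above 0 and 8 rose adjusted over the list alone, with 0 over all genes (median 0.18, camera adjusted p = 0.000195). Serpina1b, an alpha-1-antitrypsin gene, averaged 0.70 ± 0.24, but 0.088 with the dye profile subtracted, and Itih2 averaged 0.45 ± 0.26. Of 15 cholesterol synthesis genes, 12 lay above 0, 1 rose over all genes and 3 adjusted over the list alone (camera adjusted p = 0.0158, fry adjusted p = 0.0186). Beside Sc5d, Pmvk averaged 0.60 ± 0.37 and Msmo1 0.43 ± 0.27. In the list of fatty acid and triglyceride synthesis, 8 of 32 genes rose and 1 fell adjusted over the list alone, with 0 over all genes (fry adjusted p = 0.0249, camera adjusted p = 0.158), and Scd1, the stearoyl-CoA desaturase, averaged 0.64 ± 0.19. The mitochondrial respiratory chain (camera adjusted p = 0.00223) and cell cycle genes (camera adjusted p = 0.0158) stood higher, and granulocyte (camera adjusted p = 0.0331) and cholangiocyte markers (camera adjusted p = 0.0462) lower, with Lcn2 at -0.36 ± 0.18 and Cftr at -0.42 ± 0.32, or -0.078 with the dye profile subtracted. None of the members of these 4 lists passed over all genes, and adjusted over the list alone 2 respiratory chain genes rose and 1 fell, 1 cell cycle gene rose, 1 granulocyte gene fell and 0 cholangiocyte genes passed. The granulocyte median lay below 0 in 4 embryos and above it in embryos 3 and 6, at 0.19 and 0.06. The cholangiocyte median lay below 0 in 5 embryos and above it in 1. After subtraction of the adult dye profile camera called none of the 7 lists. Their medians kept their sign, at 0.13 for ribosomal proteins, 0.045 for hepatocyte secreted proteins, 0.056 for the respiratory chain, 0.32 for cholesterol synthesis, 0.11 for the cell cycle, -0.11 for granulocytes and -0.16 for cholangiocytes, against 0.20, 0.18, 0.11, 0.10, 0.07, -0.15 and -0.23 before.

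In adult mutant liver no gene passed, Afp included. Afp averaged -0.03 ± 0.19 (n = 6), Alb -0.59 ± 0.57 and Afm -0.17 ± 0.24, with adjusted p = 0.944, 0.639 and 0.689. The Afp ratio thus left the knockout labelled for the adults unchecked. The limma test passed 0 of 17039 features after adjustment, while 1314 (7.71%) had an unadjusted p under 0.05. The 5 named genes with the smallest p, none of which passed (each with adjusted p = 0.639), were Psmd14 at 1.26 ± 0.29 (n = 5), Vmp1 at -0.74 ± 0.21, Alcam at -0.53 ± 0.15, Mccc1 at 0.74 ± 0.33 and Tat, the tyrosine aminotransferase, at -0.89 ± 0.44 (n = 6 each). Of the sex-linked check genes, Kdm5d averaged 0.88 ± 1.44, with animals from -0.91 to 2.73, and Zfy1 0.03 ± 0.22 (n = 6 each, adjusted p = 0.663 and 0.926).

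By camera with its preset correlation, 12 lists were called in the adults, none of which held with an estimated correlation (smallest adjusted p = 0.465) or by fry. Of 28 adult genes for hepatocyte secreted proteins, 27 had a mean below 0, with 0 passing over all genes and 4 falling with adjustment over the list alone (median -0.31, camera adjusted p = 6.63e-10). Apoe averaged -0.56 ± 0.30, Rbp4 -0.54 ± 0.32 and F2, prothrombin, -0.53 ± 0.32. Of 27 cytochrome P450 and conjugation genes, 21 lay below 0 and 0 passed on either adjustment (median -0.35, camera adjusted p = 3.65e-06), with Cyp3a11 at -0.71 ± 0.61. Of 26 amino acid and urea cycle genes, 22 lay below 0, with 0 over all genes and 4 falling adjusted over the list alone (camera adjusted p = 3.65e-06). Arg1, the arginase of the urea cycle, averaged -0.64 ± 0.33 and Asns -0.95 ± 0.47. Camera also called the mitochondrial respiratory chain (52 of 62 genes below 0), ribosomal proteins (49 of 56), proteasome, male-biased liver genes, oxidative stress, glucose metabolism, fatty acid oxidation and endoplasmic reticulum chaperones as lower and female-biased liver genes as higher. Over all genes 0 members of these lists passed, and adjusted over the list alone 1 proteasome gene rose and 1 fell, 1 male-biased gene fell and 1 glucose metabolism gene fell. From the 5 animals with both dyes, the calls of female-biased genes (adjusted p = 0.0512) and of endoplasmic reticulum chaperones (adjusted p = 0.0971) ended, the other 10 stayed and 3 were new, with endothelial markers (median -0.15, adjusted p = 0.00303), heat shock proteins (adjusted p = 0.0487) and fatty acid and triglyceride synthesis (adjusted p = 0.0487) lower. The list medians differed between animals. For hepatocyte secreted proteins animals 1 and 2 stood at 0.14 and -0.07, and animals 3, 4, 5 and 6 at -0.64, -0.59, -0.27 and -0.59. The direction of the arrays with the mutant in Cy3 is likely, not stated by the labels. With those arrays turned in sign, as the rule set before the data were examined asked, 1760 features passed and none of the 12 list calls held. The 6 arrays with the mutant in Cy5 alone passed 1106 features, 994 higher and 112 lower. The 5 with the mutant in Cy3 alone passed 699, 15 higher and 684 lower, so the features that passed ran in opposite directions. The list medians, with the arrays as deposited, did not. With the mutant in Cy5 and in Cy3 they were -0.20 and -0.42 for hepatocyte secreted proteins and -0.16 and -0.18 for ribosomal proteins. For female-biased genes they were 0.13 and 0.10. Of the called lists, only endoplasmic reticulum chaperones changed sign, at -0.19 and 0.02.

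**Figure D3:**
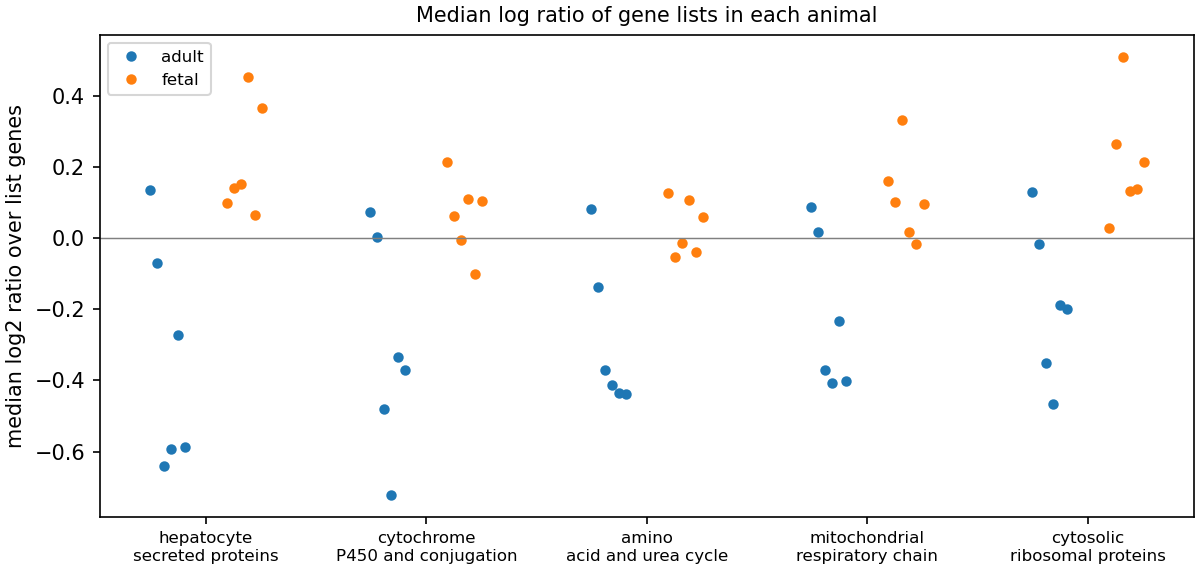
The plot shows, for 5 gene lists (horizontal axis), the median log2 ratio of mutant over pool over the genes of the list (vertical axis), with 1 point per animal, adults in blue and embryos in orange. For hepatocyte secreted proteins the 6 embryos lie above 0 and 5 of 6 adults below it.

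The adult arrays with the mutant in Cy5 were set against the fetal arrays, which share that dye layout, to ask where the log ratio of mutant over pool differed between the ages. The log ratio of Afp was higher by 8.29 in the adults, at -0.11 ± 0.23 (n = 6) against -8.40 ± 0.23 (n = 6) in the embryos (limma adjusted p = 1.45e-12). Such a ratio does not give the level of Afp in either channel, and the fetal value may be a bound set by the readings. Afm was lower in the adults, at -0.36 ± 0.45 against 0.83 ± 0.16, a difference of -1.19 (adjusted p = 0.0323). Cyp17a1, a steroid hydroxylase and lyase, was higher in the adults, at 1.03 ± 0.44 against -0.50 ± 0.33 (adjusted p = 0.0190), with an adult dye profile of 0.76, and Psma1, a proteasome subunit, lower, at -0.81 ± 0.36 against 0.35 ± 0.20 (adjusted p = 0.0248). In all, 23 of 16314 features passed, 15 higher and 8 lower in the adults, of which 13 were named genes.

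The other named genes higher in the adults were Raver2 by 2.22, Sfxn2 by 0.98, Mybpc2 by 0.93, Bzw2 by 0.92, Luzp1 by 0.83 and Iffo1 by 0.83. Those lower were Hes7, a transcriptional repressor, by -1.16, Cnp by -0.84 and Ptbp3 by -0.77. With the adult means over both dyes, a setting in which a shared dye effect no longer cancels, only Afp and Afm of the 13 named genes passed. There the difference was 1.32 for Raver2, 0.90 for Cyp17a1, 0.58 for Sfxn2, 0.39 for Mybpc2, 0.22 for Bzw2, 0.55 for Luzp1, 0.37 for Iffo1 and -0.47 for Cnp, and the adult dye profile of these genes was 1.09, 0.76, 0.48, 0.65, 0.85, 0.34, 0.55 and -0.45. Hes7 at -1.01 (adjusted p = 0.0686), Psma1 at -1.02 (adjusted p = 0.0546) and Ptbp3 at -0.65 (adjusted p = 0.0793) missed the threshold with a difference about as large. Camera with its preset correlation placed 7 lists lower in the adults, and none held with an estimated correlation (smallest adjusted p = 0.645). They included ribosomal proteins (49 of 56 genes lower, 0 passing over all genes and 7 falling adjusted over the list alone, camera adjusted p = 2.27e-06), with Rps7 at -0.59 ± 0.55 against 0.58 ± 0.42, and hepatocyte secreted proteins (22 of 27 lower, 0 over all genes and 4 adjusted over the list alone, camera adjusted p = 0.000845), with Apoe at -0.63 ± 0.55 against 0.27 ± 0.24. Cholesterol synthesis was lower by camera (adjusted p = 0.00883) and fry (adjusted p = 0.0265), with 5 of 15 genes falling and 1 rising adjusted over the list alone and 0 over all genes. The other lists were the mitochondrial respiratory chain (adjusted p = 0.000182), amino acid and urea cycle (adjusted p = 0.00558), proteasome (adjusted p = 0.00558) and oxidative stress (adjusted p = 0.0111), where 1, 7, 4 and 4 genes fell adjusted over the list alone, 1 proteasome gene rose, and only Psma1 passed over all genes. Female-biased liver genes, with Cyp17a1 as the 1 member that passed, were higher by fry (adjusted p = 0.0485) and not called by camera (adjusted p = 0.0907, and 0.645 with an estimated correlation). Pools and ages changed together, and leaving out adult animal 1 raised the count to 1224, leaving out fetal animal 5 to 78, and leaving out any other animal gave 4 to 18. The animal means over both dyes gave 9, of which 4 were among the 23.

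Female and male mutant embryos were compared because the series held both sexes. All 3 females and 1 male had a pool labelled female, and the other 2 males had a pool labelled male and another letter in their animal labels, so sex largely coincided with both. Afp lay at -8.31 ± 0.20 (n = 3) in females and -8.49 ± 0.26 (n = 3) in males, and Afm at 0.85 ± 0.20 and 0.80 ± 0.15, and limma passed neither difference (adjusted p = 0.998 and 0.999). Of 17212 features, 2 passed, Pemt, the hepatic phosphatidylethanolamine methyltransferase, and an unnamed row. Pemt stood at 16.8, 16.3 and 16.4 in the 3 males and at -0.07 and 0.94 in 2 females, with no value in the remaining female. Each of the 3 male values was the largest on its array, so no size of the difference can be given. The count was 0 when values beyond 10 in size were left out, 1 without embryo 1, 4 without embryo 2, 3 or 5, and 0 without embryo 4 or 6. Without embryo 4 or 6, or without values beyond 10, Pemt had too few values to be tested. It passed in the 4 fits with an embryo left out that tested it. Other genes with a small p that did not pass were Mob1a at -1.56 ± 0.32 in females against -0.10 ± 0.12 in males (n = 3 each, adjusted p = 0.715), Tmem14c at 0.39 ± 0.53 against -2.35 ± 0.61 (adjusted p = 0.721), Ankrd61 at 1.26 ± 0.10 against -0.32 ± 0.06 (n = 2 each, adjusted p = 0.998) and Krt19 at -0.97 ± 0.17 against 0.25 ± 0.30 (adjusted p = 0.998).

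Among the lists, camera with its preset correlation made 6 calls, none of which held with an estimated correlation (smallest adjusted p = 0.574) or by fry. It placed hepatocyte secreted proteins higher in females (21 of 27 genes, median 0.19, adjusted p = 0.00229) and the mitochondrial respiratory chain (47 of 62 genes lower, adjusted p = 0.00147), ribosomal proteins (41 of 56 lower, adjusted p = 0.00615) and megakaryocyte markers (5 of 6 lower, adjusted p = 0.00859) lower. The estrogen list was higher (adjusted p = 0.0450), where Igfbp1, an insulin-like growth factor binding protein, averaged 1.63 ± 0.06 in females and 0.29 ± 0.60 in males and was the 1 member that rose adjusted over the list alone. Cholangiocyte markers were lower (adjusted p = 0.0450), with 1 gene falling adjusted over the list alone. No member of the 6 lists passed over all genes, and no other member adjusted over its list alone. The ribosomal list median was 0.03, 0.26 and 0.51 in males 1 to 3 and 0.13, 0.14 and 0.21 in the females. Male 1 thus lay below every female. The megakaryocyte median was 0.16, 0.07 and 0.48 in the males and 0.03, -0.03 and 0.08 in the females. Male embryo 3 was the highest for both lists, so these 2 calls lean on it. For the respiratory chain every male lay above every female. With each array centred on its median, the calls of the estrogen list (adjusted p = 0.0535) and of cholangiocytes (adjusted p = 0.0541) ended. Groups of 3 did not overlap for 9.59% of features, against 10% by chance. Of the sex-linked check genes, Zfy1 was the only 1 with a fetal value, at -0.03 ± 0.31 in females and -0.16 ± 0.08 in males (adjusted p = 0.998), so the sex labels were left unchecked.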

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

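The tests of the 3 weighed patterns, and the limits set for the counts over other sign patterns and splits, were written after the results were seen.

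The values of 13 genes differed between adults and embryos by the test of the difference itself, adult minus fetal: Afp by 8.29, Raver2 by 2.22, Cyp17a1 by 1.53, Sfxn2 by 0.98, Mybpc2 by 0.93, Bzw2 by 0.92, Luzp1 by 0.83, Iffo1 by 0.83, Afm by -1.19, Hes7 by -1.16, Psma1 by -1.15, Cnp by -0.84 and Ptbp3 by -0.77. With the adult means over both dyes 2 of the 13, Afp and Afm, passed, and Bzw2 stood at 0.22, Iffo1 at 0.37 and Mybpc2 at 0.39, while Hes7 at -1.01, Psma1 at -1.02 and Ptbp3 at -0.65 missed the threshold with a difference about as large. Afp passed in 12 of 12 fits that left out an animal, Hes7 and Cnp in 6 and Afm in 2. Pemt differed between female and male embryos by a recorded -16.08, which is no measured size, since its 3 male values were the largest on their arrays.

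Among 106 sets of values tested for a sample far from the others, 7 had one, where chance alone gives about 1 in 20. In adult animal 6, Afp stood at 0.34, with the others between -0.19 and -0.00, and Cyp4a14 at -0.58, with the others between 0.20 and 0.63. Alcam stood at -0.81 in adult animal 3, Hnf4a at -0.033 in adult animal 1 and Psmc6 at -1.71 in adult animal 5. The array of fetal animal 6 had 302 missing values, against 97 to 148 on the other fetal arrays. The array of adult animal 1 with the mutant in Cy5 had an SD of 0.675, against 0.918 to 1.05 on the other arrays of that orientation.

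The real sign pattern gave 26 fetal features and no other of 32 gave more than 1, so 1 of 32 was as large, the smallest share this test can reach. Random signs of the arrays thus did not give such a count. A dye effect or a deviation of the wild-type pool, shared by all embryos, is not excluded by it. For adult minus fetal, 1 of 100 splits gave as many as 23, and the highest other gave 0. Random splits of the arrays thus did not give such a count. Pool and age changed together with the real split, so the count does not tell their effects from that of the mutation. In the adults the real count was 0, so 32 of 32 patterns gave as many by construction (highest other 0), and nothing follows about chance. For the sexes, 7 of 10 splits gave as many as 2, with a median of 2 and a highest of 4 over the other splits. A count of 2 was thus common among splits of these embryos, although 10 splits are too few for a share under 0.05.

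The fetal values sat 11 rows from their probe names. An embryo set without the knockout was argued against by the size of the Afp value, -8.40 under the moved names, against 0.14 under the deposited names. Its sign cannot bear on this, since the direction of the ratios rests on that same value. A displacement of the fetal rows remains the candidate explanation, since 20 of 21 probe blocks shared the offset. No biological explanation was tested.

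Opposite-dye adult arrays correlated negatively. Columns that were not yet turned are argued against by same-gene probes, whose rank correlation was higher in the mean of both dyes than in the dye profile by 0.0568, with an SD of 0.0206 over resampled genes. Dye bias of single probes may account for the pattern: of 1108 same-gene pairs with a probe that passed after turning, 38.5% shared a sign in the dye profile, against 40.2% with shuffled partners. This test cannot decide, since passing after turning rests on the same dye profile. Same-gene probes also agreed little in the mean of both dyes, at a rank correlation of 0.0552. The negative within-animal correlation over all probes, -0.101, goes the other way, and no biological explanation was tested.

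Cela2a and Cpa1, genes of the acinar pancreas, were lower in the fetal arrays, at -1.30 and -1.17, while the exocrine pancreas list was not called (camera adjusted p = 0.231). Neither gene passed in any fit that left out an embryo. Dye bias as measured in the adults is argued against as the whole cause, by the last of 3 tests tried: after subtraction of the dye profile Cela2a stood at -1.08 and Cpa1 at -0.68, and at -1.28 and -1.11 after the scaled one, each below 0 by over 2 errors with that of the profile included, although Cpa1 then missed the threshold (adjusted p = 0.0529). Pancreas tissue in the wild-type pool could account for the 5 genes of the list below 0 in every embryo, Cela2a, Cpa1, Cela3b, Rnase1 and Ctrb1, the lowest at -1.85 (adjusted p = 0.0558), but 3 genes, Clps, Spink1 and Pnliprp2, lay above 0 in every embryo. The adult dye profile was as large as the fetal mean for Rnase1 (both -0.56) and larger for Pnliprp2 (0.42 against 0.31), so neither gene bears on the pool. Spink1 was also on the list of fetal liver genes. Since the pool cannot be examined on its own, tissue in the pool and an effect of the mutation cannot be told apart, and the latter was not tested.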

How the results depend on the processing

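No paired analysis was possible because the adult numbers in the labels count hybridisations, not animals, so the numbers that also stand on embryos denote no pairs. Alternatives chosen after seeing the data are marked as added. Causes of the changes below were not tested unless named.

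The adult count of 0 stayed at 0 under centring, scaling, single probes, the block and balanced fits and each left-out animal, and became 1106 with the mutant in Cy5 alone, 699 with the mutant in Cy3 alone and 1760 with the arrays turned (added). The fetal count of 26 became 2 at adjusted p under 0.01, 12 with scaling (7 higher and 5 lower, against 10 and 16), 88 for single probes, 61 for complete features, 81 with the robust variance model, 83 without values beyond 10 in size (added), 13 with sex as a covariate, 2 without the male embryo with a pool labelled female and 4986 after dye subtraction, where the subtracted profile and its error are the same in each embryo. With the profile scaled to each embryo (added) it was 22. The adult minus fetal count of 23 became 4 at adjusted p under 0.01, 36 for complete features, 40 with the robust model, 42 without values beyond 10 (added), 9 with animal means, 11 with male embryos alone and 1579 with the fetal rows named as deposited (added). The sex count of 2 became 1 at adjusted p under 0.01, 1 with the robust model, 4 without the male embryo with a pool labelled female, and 0 with scaling, for complete features and without values beyond 10 (added). Pemt was not tested for complete features or without values beyond 10, for want of values. Leaving out each animal in turn gave 0 to 0 in adults, 2 to 5 in embryos, 4 to 1224 for adult minus fetal and 0 to 4 for the sexes.

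The 32 list calls became 0 with an estimated correlation, 6 by fry, 20 with the arrays turned and 12 with the fetal rows named as deposited (the last 3 added). After dye subtraction Ddx3x stood at -0.037, Rpl9 at -1.41 and Gmnn at -0.76. With the fetal rows named as deposited, values moved to other probes: Afp stood at 0.14, Ddx3x at -0.48, Sc5d at -0.063, Prap1 at 0.094, Cpa1 at 0.25 and Dhrs7 at 0.0535, Afp in adult minus fetal at -0.25 and Pemt between the sexes at 0.18. Of the other fetal gene values outside the fits that left out an animal, 446 kept their side of the threshold, 36 no longer passed and 24 newly passed. Signal over background is unknown, so the precision of single values is as well.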

Other observations

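The list tests were planned, and Hba-a1, Car1 and the single probes were named after their values were seen. In the embryos, of 28 erythroid genes 12 lay above 0 and 16 below, with Hba-a1 at -0.23 and Car1 at 0.62, and camera did not call the list (adjusted p = 0.827). The adult interferon, cell cycle and circadian lists had medians of -0.00, -0.03 and -0.03, and camera called none of them. Hba-a1, the adult alpha-globin gene, averaged -0.38 ± 0.45 (SD, n = 6) in adults and did not pass.

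Probe 19614, which has no gene symbol, was the only other fetal feature below -4 in all 6 embryos, beside the 3 Afp probes. It averaged -5.62 ± 0.50 in embryos and -0.07 ± 0.17 in adults, and passed in 6 of 6 fits that left out an embryo. Afp probes 19612 and 19709 both read -8.45 in embryo 4 and in embryo 5, and both read -8.75 in embryo 1. On each fetal array the lowest value was that of an Afp probe. Probe 19729 of Afp stood a whole log2 unit above them in embryo 1, at -7.75, and in embryo 5, at -7.45. Equal values and whole steps go with readings at a limit, so the size of the Afp change may be a bound. Its SD may reflect rounding. The ratios do not show the floor of the mutant channel, and whether such a limit also holds for probe 19614 is unknown.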
